A study of Homo sapiens with 6 samples.

How the data were processed

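The series holds 6 RNA-seq libraries of human multiple myeloma lines: the parental lines KMS21, KMS27 and KMS34 and a lenalidomide-resistant derivative of each. Per the labels, cells grew in RPMI1640 with serum, the resistant lines stayed in low lenalidomide, total RNA was taken with QIAzol and a miRNeasy kit, and libraries were made with a TruSeq stranded mRNA kit. The submitters' processing notes name FastQC, TopHat and Partek and the genome build hg19, without versions; the order of the steps, the counter, the annotation and any filter are not given in the sources used here.

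The authors deposited a table of 15292 genes by 6 libraries. Its header names neither unit nor scale. The values are log2 of a normalized value plus 1, as the deposited numbers show: none is below 0, the highest is 12.9, and 10 of 10 tiny values were whole multiples of the rounding step that such a logarithm leaves (tolerance 0.0001). The linear unit (RPKM, FPKM or TPM) is not named. Low genes step by whole multiples of a gene-specific unit, from which depth relative to KMS21 was taken as 0.956, 0.869, 0.951, 0.965 and 0.941 for KMS21R, KMS27, KMS27R, KMS34 and KMS34R. In TPM the step would carry composition too, and it was sought only near equal depth, so a larger difference could have been missed. Absolute depth is unknown, so no interval from counting is given for expression. The linear sums were 298397, 289053, 401331, 268590, 266602 and 267610 for KMS21, KMS21R, KMS27, KMS27R, KMS34 and KMS34R, and the 100 highest genes held 41.6%, 27.7%, 52.9%, 32.2%, 25.6% and 24.7% of them. All columns were matched to samples by label, leaving 0 without a sample.

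From this table, log2(value + 1) was tested with limma 3.58.1 in R 4.3.3, with a trend, robust empirical Bayes and cell line as a covariate, on the 9031 genes with a linear value of at least 1 in at least 3 of 6 libraries. Tests were two-sided with Benjamini-Hochberg adjustment at 0.05. Fold changes on this scale understate the change of low genes, and a gene at 0 is only said to be listed at 0. Cell line is in the model because each resistant line comes from 1 parental line. Deviations from the group means correlated at 0.52 for the KMS27 pair and 0.69 for the KMS34 pair, but at 0.04 for the KMS21 pair, and the pairing rests on the labels. The design had planned a count-based test for counts and this test for normalized values. Residual degrees of freedom were 2 and limma's prior added 12.5, so the spread assumed for a gene comes mostly from other genes; the median SE was 0.43.

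Lists of genes were tested with limma's camera at a preset correlation of 0.01, again with an estimated correlation, and with fry. Of 36 lists, 8 were not tested: T and NK cell, myeloid, fibroblast and stromal, endothelial, epithelial and erythroid markers, the mitochondrially encoded transcripts and the genes the study named, each with under 5 tested members. Genes at least 2-fold different were counted within each line, and those shared by all 3 lines were set against the number expected for independent lines. The groups, tests, lists, alternatives and the rule for named genes were fixed before the data were examined.

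Genes are named by this rule: (a) up to 10 per direction with the largest change among those that pass and go the same way in all 3 lines, filled up, where fewer pass, with genes at least 2-fold different in the same direction in all 3 lines, ranked by their smallest ratio; (b) SORT1, LAMP2, CRBN, IKZF1, IKZF3, IRF4 and MYC; (c) up to 4 passing members of each list or, failing these, up to 2 members that went the same way in all 3 lines; (d) the 3 highest and 3 lowest ratios of each line among the tested genes; (e) the translocation targets. Unnamed loci and XIST and genes on the Y chromosome were passed over. NSD2 was not analysed here.

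Alternatives were the model without cell line, quantile normalization, median-ratio scaling, limma without trend, no filter on low genes, a filter on a mean of at least 5, pseudocounts of 0.1 and 0.01, thresholds of 1.5-fold and 4-fold, ratios centred on their median, and leaving out each line. Leaving KMS21 out of the shared count was added after the data were seen.

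Tested on simulated data with 9031 genes in 5 draws, the gene test of resistant against parental lines recovered 6.8% of 250 genes seeded at 2-fold, 80.4% of 250 at 4-fold and 99.6% of 250 at 8-fold and at 16-fold, and 109 of its 825 calls (13.2%) were false, above the nominal 5%. Each simulated gene had the same spread in all libraries and the same change in every line. The real line ratios had SDs of 1.20, 0.82 and 0.49 in KMS21, KMS27 and KMS34. The shares recovered may therefore not hold for the real data, and finding no gene does not exclude shared changes of these sizes. The list test found 20 of 20 shifted lists and called 1 of 540 unshifted lists among simulated independent genes. Symbols were matched to a RefSeq table, 14580 as current and 527 as older names of 15292. The reference annotation is of GRCh38 and the table of hg19, so no coordinates are printed; transcript lengths came from that annotation. Python 3.11.15 with matplotlib 3.10.9 drew the plots.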

Results

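RNA was sequenced from 3 human multiple myeloma lines, KMS21, KMS27 and KMS34, and from the derivative of each that had been kept in lenalidomide for a long period, KMS21R, KMS27R and KMS34R. Multiple myeloma is a cancer of plasma cells, and lenalidomide is a drug that binds cereblon and directs the transcription factors IKZF1 and IKZF3 to degradation. Per the labels, the derivatives stuck to the dish and had taken on a spindle form. There was 1 library per line and state, which gave 3 parental and 3 resistant libraries, and 15292 genes in the table. Between 8043 genes (KMS27) and 9232 genes (KMS34R) had a linear value of at least 1. The number of reads is unknown, but low genes stepped by whole multiples that put the depth of the libraries between 0.869 (KMS27) and 1 relative to KMS21, if the linear unit is not one that also carries composition. This step was sought only near equal depth, so a larger difference could have been missed.

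The libraries were first compared with each other, to see how closely each derivative resembled its parental line. Over the 9031 tested genes, Pearson's r was 0.961 between KMS34 and KMS34R and 0.915 between KMS27 and KMS27R, against 0.748 to 0.841 for the 12 pairs of libraries from different lines. For KMS21 and the library labelled KMS21R it was 0.788, within the range of unrelated lines. Genes that were on in 1 library of a pair (log2 value of at least 3) and off in the other (under 0.3) numbered 6 in KMS34, 14 in KMS27 and 245 in KMS21, against 165 to 267 between lines. These correlations run across genes, which are not independent replicates. The KMS21 pair thus entered the comparisons over 3 lines with the size of a difference between lines.

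**Figure D1:**
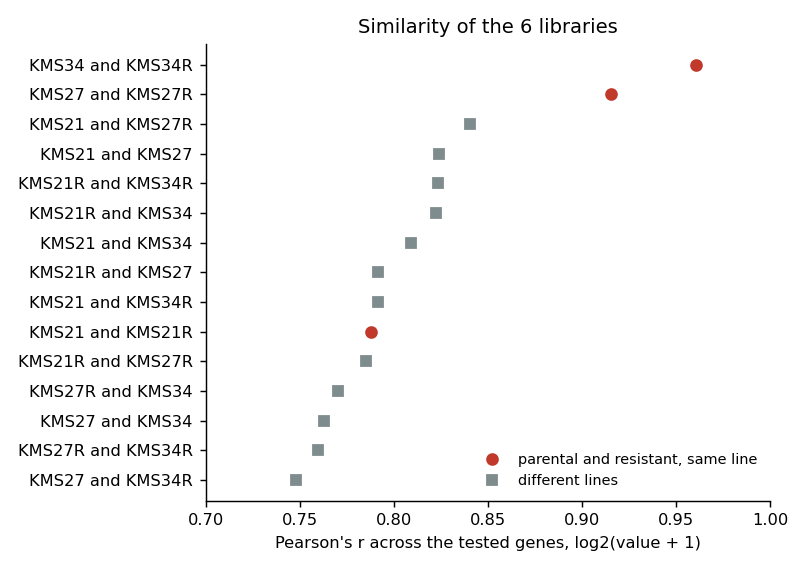
Pearson correlation of log2(value + 1) over 9031 genes for each of the 15 pairs of libraries, with red circles for a parental line and its derivative and grey squares for libraries of different lines. The KMS34 and KMS27 pairs lie at 0.961 and 0.915, and the KMS21 pair lies at 0.788, among the 12 pairs of different lines.

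Genes that chromosomal translocations switch on in myeloma were read to describe the lines. CCND1, the D-type cyclin placed under the immunoglobulin enhancer by a common translocation, had a log2 value of 7.25 in KMS21 and 4.11 in the library labelled KMS21R, 7.07 in KMS27 and 7.62 in KMS27R, and at most 0.08 in KMS34 and KMS34R. CCND2, another D-type cyclin, was listed at 0 in KMS21 and stood at 7.38 in the library labelled KMS21R, with 2.79 and 3.55 in KMS27 and KMS27R and 4.86 and 5.54 in KMS34 and KMS34R. FGFR3, a growth factor receptor, was at 0.03 in KMS21 and 7.76 in the library labelled KMS21R, and at 6.08 in KMS34 and 3.29 in KMS34R. MAF, a transcription factor, was listed at 0 in KMS21 and in both KMS27 libraries, and was at 3.56 in the library labelled KMS21R and at 4.32 and 4.30 in KMS34 and KMS34R. MYEOV was at 5.31 and 5.92 in the KMS21 libraries, listed at 0 in both KMS27 libraries, and at 2.66 and 0.47 in KMS34 and KMS34R. CCND3 lay between 2.71 and 4.65 in the 6 libraries, while MAFA stayed under 1 in all of them. The list of these genes did not pass (adjusted p = 0.669, camera), although without KMS34 it moved up relative to other genes (adjusted p = 0.0362, on 2 lines). Its median was 0.93 in KMS21 and 0 in KMS27, so that call leaned on the KMS21 pair.

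**Figure D2:**
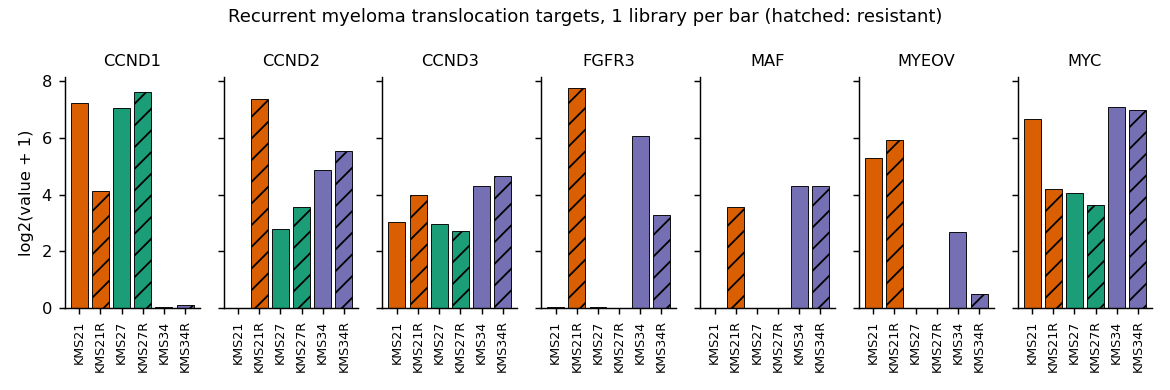
Log2(value + 1) of 7 translocation target genes in each of the 6 libraries, with plain bars for parental and hatched bars for resistant libraries. FGFR3 stands at 0.03 in KMS21 and 7.76 in the library labelled KMS21R, and CCND1 at 7.25 and 4.11.

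The main comparison asked which genes differed between resistant and parental cells in the same way in all 3 lines. Per the labels, the resistant lines stayed in low lenalidomide and had taken on an adherent spindle form. Resistance therefore cannot be told apart from the presence of the drug or the growth form in any comparison here. Among the genes at least 2-fold higher in each resistant library, LGALS3BP, a secreted glycoprotein that binds galectins, had a log2 difference of 2.68 ± 0.44 (SE, n = 3 lines), with line ratios of 3.57, 1.95 and 2.52 in KMS21, KMS27 and KMS34. SORT1, which encodes sortilin, a receptor that sorts proteins between the Golgi and endosomes, differed by 2.25 ± 0.45, and BLVRA, biliverdin reductase, by 2.13 ± 0.42. CHST2, a sulfotransferase of glycans (2.09 ± 0.44), IFI6, an interferon-induced gene (2.05 ± 0.40), ITGB5, an integrin beta chain that takes part in binding vitronectin (2.02 ± 0.43), RHOBTB3 (2.01 ± 0.41), and NFKBIZ, a nuclear regulator of NF-kB (1.88 ± 0.43), followed. KDELC2, now named POGLUT3, was listed at 0 in KMS21, and SLC12A7, a potassium and chloride cotransporter, was listed at 0 in KMS21 and KMS34; their resistant libraries stood at 3.41, 4.197 and 4.09 and at 1.46, 2.38 and 2.56.

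Among the genes at least 2-fold lower in each resistant library, LEFTY2, a secreted factor of the TGF-beta family, had a log2 difference of -3.66 ± 0.72 (SE, n = 3 lines), CD53, a tetraspanin of leukocytes, -3.16 ± 0.65, and ITGAL, the alpha chain of the leukocyte integrin that binds ICAM proteins, -2.80 ± 0.84. The ITGAL value rested on the KMS21 pair, with line ratios of -5.28, -1.37 and -1.75 and -1.56 without KMS21. LEFTY2 and CD53 also leaned on that pair, and differed by -2.59 and -2.14 without it. ICAM2, a ligand of the integrin that holds ITGAL, differed by -1.36 ± 0.39 and CORO1A, an actin-binding protein of blood cells, by -1.78 ± 0.46, or by -1.21 without KMS21. HOMER3, a scaffold protein (-2.21 ± 0.48), and ANKRD37, a target of the hypoxia factor HIF (-1.73 ± 0.42), were also lower in each line, and PLA2G16, now PLAAT3, a phospholipase, was at 0.44 in the library labelled KMS21R, listed at 0 in KMS27R and at 2.30 in KMS34R, from 4.95, 3.48 and 3.44 in the parental lines.

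None of these genes passed the test. With limma, 0 of 9031 genes had an adjusted p under 0.05, the smallest being 0.225 for LGALS3BP, and 466 had an unadjusted p under 0.05, 376 higher and 90 lower, where 451.55 were expected by chance. limma without its trend also gave 0, with 473 at the unadjusted threshold. The other 17 genes named above had adjusted p-values from 0.306 to 0.884. The count rested on which lines were used: leaving out KMS21 gave 25 genes (15 higher and 10 lower), leaving out KMS34 gave 89 (50 and 39) and leaving out KMS27 gave 0, each on 2 lines with 1 residual degree of freedom. LGALS3BP, RHOBTB3, IFI6, BLVRA, ITGB5, SLC12A7, LEFTY2, CD53, HOMER3 and PLA2G16 were among the 25, and LGALS3BP, KDELC2, SORT1, LEFTY2, CD53, ITGAL, HOMER3 and PLA2G16 among the 89. These genes were picked for 2-fold ratios in the same libraries, so their place there adds no support. Some calls rested on 1 line. COX7B2, among the 25, was listed at 0 in both KMS34 libraries, and CD81, TMEM54 and MOXD1, among the 89, at 0 in both KMS27 libraries. Most genes leaned up, with a median log2 difference of 0.25 and 73.7% of genes above 0. Quantile normalization brought that share to 50.3% and median-ratio scaling to 49.9%, with medians of 0.003 and -0.001. The fitted differences of single genes are thus to be read against 0.25. Ratios within a line are to be read against that line's own median, 0.30, 0.43 and 0.02 in KMS21, KMS27 and KMS34.

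With 1 library per line and state, and no label that speaks of separate cultures, these p-values hold no spread between cultures of a line. They rest on the spread between the 3 lines, drawn mostly from other genes (2 residual and 12.5 prior degrees of freedom). An exact two-sided test on 3 pairs could not give a p below 0.25.

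**Figure D3:**
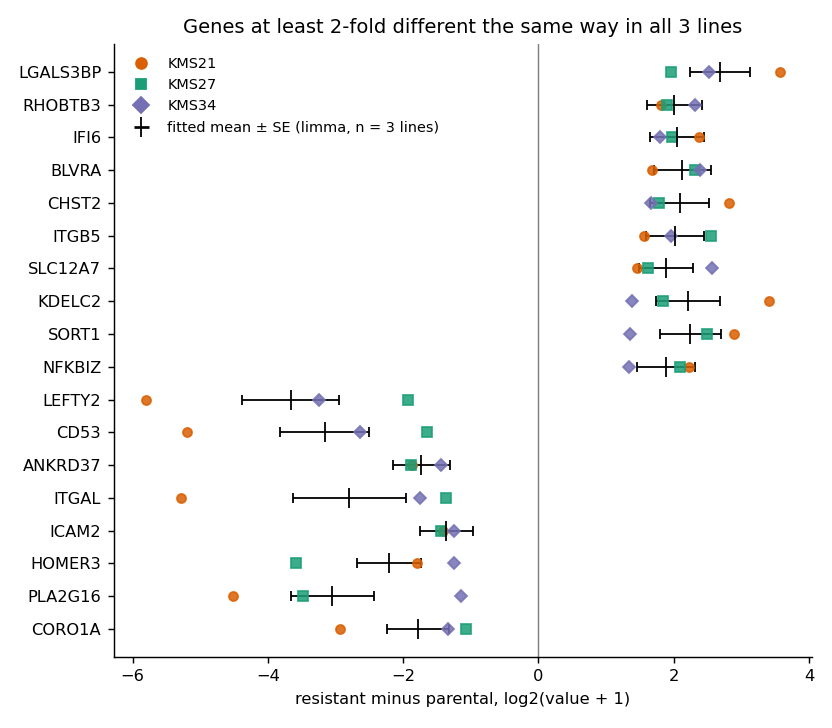
Log2 ratio of resistant over parental library for 18 genes that were at least 2-fold higher or lower in all 3 lines, with an orange circle for KMS21, a green square for KMS27, a purple diamond for KMS34 and a black mark with bar for the fitted mean ± SE (limma, n = 3 lines). LGALS3BP lies at 2.68 and LEFTY2 at -3.66, and no gene shown passed the adjusted threshold.

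Genes of the drug's own pathway and the genes the study singled out were read in each line. IKZF1, the lymphoid transcription factor that lenalidomide sends to degradation, was higher in each resistant library, with a log2 difference of 1.63 ± 0.42 (SE, n = 3 lines) and line ratios of 1.98, 1.87 and 1.03 in KMS21, KMS27 and KMS34. IKZF3, its relative and the other target, had ratios of -0.43, 1.83 and -0.05. CRBN, the cereblon gene itself, differed by -0.05 ± 0.43, with ratios of 0.09, 0.35 and -0.61, and its direction turned without KMS34 (0.22). IRF4, a plasma cell transcription factor, had ratios of -0.33, 1.11 and 0.10, and MYC, a growth regulator, -2.45, -0.43 and -0.10. The fitted differences of IKZF3 and IRF4 turned from 0.45 to -0.24 and from 0.29 to -0.11 without KMS27. LAMP2, a protein of the lysosome membrane, differed by 1.17 ± 0.43 with ratios of 1.96, 1.20 and 0.35, or by 0.78 without KMS21, and SORT1 by 2.25 ± 0.45. The study named SORT1 and LAMP2 from these same samples, so neither is independent evidence of its direction. None of the 7 passed in limma, with adjusted p-values from 0.306 for SORT1 to 0.982 for CRBN, and SORT1 had an adjusted p of 0.0977 without KMS21, 0.901 without KMS27 and 0.0101 without KMS34, in a range of 0.0101 to 0.9995 over 11 alternatives.

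**Figure D4:**
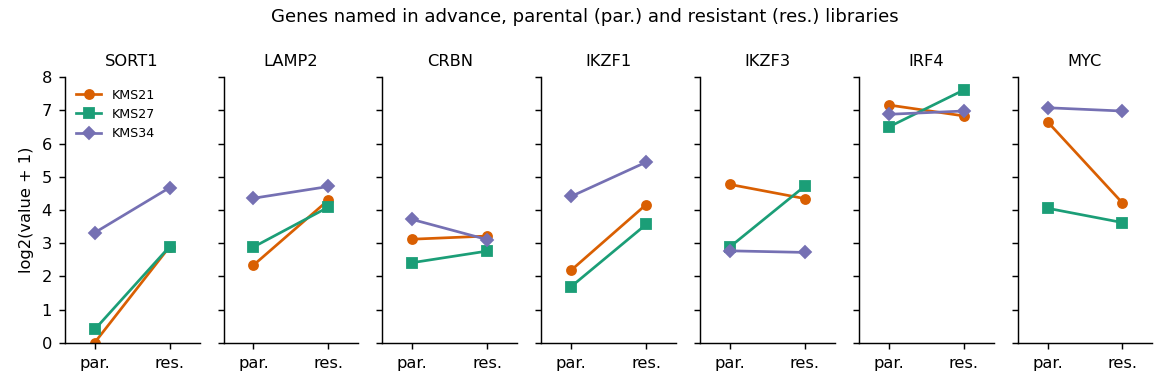
Log2(value + 1) of SORT1, LAMP2, CRBN, IKZF1, IKZF3, IRF4 and MYC in the parental and resistant library of each line, joined by a line per cell line. IKZF1 and SORT1 are higher in all 3 resistant libraries (IKZF1 ratios 1.98, 1.87 and 1.03), and CRBN has ratios of 0.09, 0.35 and -0.61.

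Lists of genes fixed beforehand were tested for whether their members moved together relative to other genes. Of the 36 lists, 28 had at least 5 measured members. With camera's preset correlation of 0.01, 9 passed, 5 up and 4 down. With an estimated correlation 0 passed, the lowest adjusted p being 0.722, and with fry, which does not compare a list with other genes, 1 passed. The directions are relative to other genes, whose median was 0.25, so a list can be called down with a median near 0. Over all tested genes, 24.1% were higher and 4.62% lower in all 3 lines, which is the background for the counts of list members.

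Interferon response genes moved up relative to other genes (adjusted p = 3.06e-06, and 0.722 with an estimated correlation). Of the 21 tested members, 11 were higher in all 3 lines and 0 lower in all 3, the median log2 difference was 0.85, and the line medians were 1.31, 1.03 and 0.42 in KMS21, KMS27 and KMS34, or 1.03, 0.50 and 0.40 with median-ratio scaling. No member passed over all genes tested, while 8 passed adjusted over the list alone, among them IFI6, IFITM1, IFIT3, IRF9, ISG15, PARP9 and OAS1. IFIT3, an antiviral protein, had a log2 difference of 1.49 ± 0.39 (SE, n = 3 lines), and was higher in each line, with ratios of 1.27, 1.53 and 1.69. The call held without each line in turn, with adjusted p-values of 2.39e-05, 7.68e-05 and 0.000308 without KMS21, KMS27 and KMS34.

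Genes of class II antigen presentation, which display peptides to helper T cells, also moved up (adjusted p = 1.70e-05, and 0.748 with an estimated correlation), but in KMS21 and KMS27 rather than in KMS34. Their line medians were 3.22, 2.79 and -0.11, and of the 9 tested members only CD74, the invariant chain, was higher in all 3 lines (log2 difference 1.58 ± 0.51, SE, n = 3 lines). CIITA, the master regulator of these genes, had ratios of 3.15, 3.16 and -0.28, and was chosen after its values were seen. The difference between the lines was not tested. Without cell line in the model the list had an adjusted p of 0.0580, and over its 11 alternatives from 2.51e-21 to 0.748. HLA genes resemble each other closely, so reads could be split between them, and single values are uncertain.

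Lysosome and endosomal sorting genes moved up (adjusted p = 0.00520, and 0.748 with an estimated correlation). Among 44 tested members 19 were higher in all 3 lines and 0 were lower in all 3, with line medians of 0.56, 0.69 and 0.20, or 0.22, 0.16 and 0.19 with median-ratio scaling. SORT1 was the only member that passed adjusted over the list alone, and GRN, the progranulin gene, a sortilin ligand, had a log2 difference of 1.13 ± 0.41 (SE, n = 3 lines). SORT1 and LAMP2 belong to this list and were picked by the study from these libraries. Without KMS27 the list had an adjusted p of 0.0692, within a range of 0.000308 to 0.748 over its 11 alternatives.

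Actin cytoskeleton and focal adhesion genes, through which cells hold to a surface, moved up (adjusted p = 0.00651, and 0.748 with an estimated correlation). Here 15 of 40 tested members were higher in all 3 lines and 0 lower in all 3, and the line medians were 0.99, 0.74 and 0.21, or 0.66, 0.21 and 0.195 with median-ratio scaling. VCL, vinculin, a protein of adhesion sites, differed by 1.20 ± 0.44 and MYH9, a non-muscle myosin heavy chain, by 1.24 ± 0.42 (SE, n = 3 lines). Cell cycle genes moved up as well (adjusted p = 0.0145, and 0.831 with an estimated correlation), with 13 of 39 higher in all 3 lines and line medians of 0.82, 0.63 and 0.05, or 0.48, 0.08 and 0.04 with median-ratio scaling. FOXM1, a transcription factor of dividing cells, differed by 1.38 ± 0.45 and CCNB1, a mitotic cyclin, by 0.66 ± 0.42, or by 0.78 and 0.33 without KMS21. The cell cycle call was lost without KMS21 (adjusted p = 0.270), without KMS27 (0.128), with median-ratio scaling (0.0574) and with a pseudocount of 0.1 (0.0758), in a range of 0.000372 to 0.831 over 11 alternatives.

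Ribosomal protein genes moved down relative to other genes (adjusted p = 1.14e-57, and 0.722 with an estimated correlation, which was 0.79). The median log2 difference over 55 members was -1.02, with -0.41 under quantile normalization and -1.32 under median-ratio scaling. The line medians were -1.31, -1.70 and -0.09, and 35 members were lower in all 3 lines. RPS14, a protein of the small subunit, differed by -1.56 ± 0.52 and RPL14, one of the large subunit, by -0.97 ± 0.48 (SE, n = 3 lines). These genes held 24.9% of the linear sum in KMS21 and 33.7% in KMS27, against 10.7% and 15.5% in their resistant libraries, and 12.3% and 10.9% in KMS34 and KMS34R. Many have processed pseudogenes, so the values of single members are uncertain.

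Plasma cell identity genes moved down (adjusted p = 3.06e-06, and 0.722 with an estimated correlation), with 6 of 19 members lower in all 3 lines and 2 higher. MZB1, which helps antibodies to be assembled, differed by -1.76 ± 0.53 and TNFRSF17, the surface receptor BCMA, by -1.28 ± 0.44 (SE, n = 3 lines), MZB1 by -1.14 without KMS21. The line medians were -0.96, -0.10 and -0.56, and that of KMS27 turned to 0.06 with quantile normalization. Without KMS21 the adjusted p was 0.0548, in a range of 2.69e-06 to 0.722 over 11 alternatives.

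Hypoxia and glycolysis genes were called down (adjusted p = 0.00460, and 0.722 with an estimated correlation), with a median of -0.10 and line medians of -0.11, 0.11 and -0.18, of which that of KMS27 turned to -0.32 with median-ratio scaling. Of 26 members, 6 were lower and 3 higher in all 3 lines, and ANKRD37 alone passed adjusted over the list alone, while VEGFA, a growth factor of blood vessels, differed by 0.69 ± 0.40 (SE, n = 3 lines). The call was lost without KMS21 (adjusted p = 0.0785) and with quantile normalization (0.273), in a range of 0.000629 to 0.722 over 11 alternatives. Genes of the unfolded protein response, which copes with misfolded protein in the endoplasmic reticulum, were called down (adjusted p = 0.00572, and 0.748 with an estimated correlation) on the strength of KMS21. Their line medians were -0.83, 0.46 and 0.05, that of KMS27 turning to -0.09 with median-ratio scaling and that of KMS34 to -0.01 with quantile normalization. XBP1, a transcription factor of this response, was higher in all 3 lines (0.45 ± 0.45) and ASNS, asparagine synthetase, lower in all 3 (-1.31 ± 0.72, SE, n = 3 lines), though mostly in KMS21, with ratios of -3.57, -0.10 and -0.27 and -0.18 without KMS21. Without KMS21 the direction turned up with an adjusted p of 0.412, and quantile normalization (0.858) and no filter on low genes (0.113) also ended the call, in a range of 9.14e-05 to 0.936 over 11 alternatives.

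**Figure D5:**
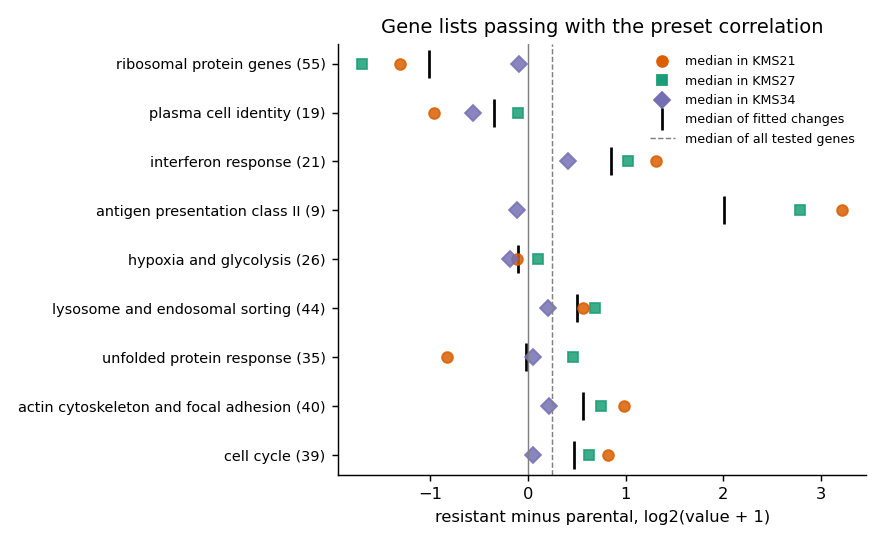
Median log2 ratio of resistant over parental library in each line (orange circle KMS21, green square KMS27, purple diamond KMS34) for the 9 lists that passed camera with the preset correlation, with a black bar for the median of the fitted differences and a dashed line at 0.25, the median of all tested genes. Interferon response lies above the line in all 3 cell lines (1.31, 1.03 and 0.42), while class II antigen presentation lies at 3.22, 2.79 and -0.11 and the KMS27 medians of plasma cell identity, hypoxia and the unfolded protein response turn sign with another scaling. The dashed line is for the fitted differences, and the medians of all tested genes by cell line were 0.30, 0.43 and 0.02.

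The other 19 lists did not pass. Cell cycle inhibitors and senescence came closest (adjusted p = 0.0682), and this was the list that passed with fry (0.0208). It moved up with quantile normalization (0.0206), in a range of 0.0206 to 0.748 over 11 alternatives, and held GADD45A, a stress-induced growth arrest gene, at 1.37 ± 0.41 and CDKN1B, a cyclin kinase inhibitor, at 1.08 ± 0.41 (SE, n = 3 lines). Cholesterol biosynthesis (0.114) was called down with quantile normalization (0.0357) and median-ratio scaling (0.0456). Integrins (0.135) held 2 members that passed adjusted over the list alone, ITGB5 and ITGB1, the latter chosen after its values were seen, and ITGAL on the lower side. In the cereblon pathway list (0.970) IKZF1 alone passed adjusted over the list alone, and CUL4A, the scaffold of the ligase that holds cereblon, differed by 0.56 ± 0.43, or by 0.32 without KMS27. Cell adhesion molecules (0.540) passed down only under the stricter filter (0.0118), and held ICAM1, a ligand of leukocyte integrins, at 1.29 ± 0.42 beside ICAM2. Mesenchymal transition (0.389) and extracellular matrix (0.792), the lists nearest to the spindle form, gave S100A4, listed at 0 in the library labelled KMS21R, with -3.86 and -0.61 in KMS27 and KMS34, ZEB1, a repressor of epithelial genes, at 0.65 ± 0.43 and at 0.29 without KMS27, and FBN1, fibrillin, at 0.69 ± 0.39, but only 5 of 39 extracellular matrix genes in the table were high enough to be tested.

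In the extracellular vesicle list (0.478), 13 of 43 members were higher in all 3 lines, VPS37A at 0.73 ± 0.41 and PLD2 at 0.70 ± 0.40 (SE, n = 3 lines) among them. WNT signalling (0.301) had BCL9 at 0.91 ± 0.42 and FZD1, a WNT receptor, at 0.77 ± 0.39, and BCL2 family and apoptosis (0.540) had BMF, a promoter of cell death, at 1.52 ± 0.42. Class I antigen presentation (0.498) had TAP1, a peptide transporter, at 1.14 ± 0.48 and at 0.53 without KMS21, and NF-kB targets (0.702) had NFKBIA, the inhibitor of NF-kB, at 0.44 ± 0.40. MAPK output (0.540) had SPRED2 at 0.99 ± 0.44 and at 0.66 without KMS27, heat shock and dissociation stress (0.702) DUSP1 at 0.51 ± 0.41, and JUN, which both lists hold, stood at 0.46 ± 0.40. Drug transporters (0.702) held ABCC10 at 0.91 ± 0.43 and ABCB9 at -0.69 ± 0.39. B cell markers (0.962) had no member that went the same way in all 3 lines. The proteasome (0.389) had line medians of 0.70, -0.31 and -0.02 and was called down without KMS21 (0.000913). Replication-dependent histones (0.389), whose transcripts mostly lack the poly(A) tail that the library kit selects, had line medians of -2.15, 0.82 and 1.497, and were called up without KMS21 (2.19e-06) and down without KMS34 (1.19e-05). For cholesterol biosynthesis, mesenchymal transition, histones, proteasome, MAPK output, cell adhesion, translocation targets, heat shock, drug transporters and B cell markers, camera's direction was down while the median or the mean of the members lay above 0.

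The next question was whether the lines shared their differences. Between lines the ratios hardly went together across genes, with Pearson's r of -0.07 (Spearman's coefficient -0.17) for KMS21 and KMS27, 0.10 (0.13) for KMS21 and KMS34 and 0.06 (0.04) for KMS27 and KMS34; genes are not independent replicates, so no p is given. In all 3 lines 28 genes were at least 2-fold higher, where 12.5 were expected had the lines been independent, and 8 at least 2-fold lower, where 0.713 were expected. With each ratio centred on its median these were 17 (2.75 expected) and 15 (2.48). Among the 28 were HMOX1, heme oxygenase, and SERPINH1, a collagen chaperone, both chosen after their values were seen, with SORT1, IKZF1, BMF, IFIT3 and IRF9. Of the 75 genes that were at least 2-fold different in every line in any direction, 36 went the same way, against 23.8 expected from the signs, and with centred ratios 32 of 61, against 15.1. By pairs of lines, KMS27 and KMS34 shared 67 higher genes (59.4 expected) and 21 lower genes (7.30), KMS21 and KMS34 shared 115 (57.2) and 42 (12.97), and KMS21 and KMS27 shared 273 (417.7) and 94 (48.4). With centred ratios these were 39 (20.6) and 32 (17.2), 96 (34.6) and 59 (21.1), and 87 (96.0) and 184 (153.6). On pairs of lines the same count was 88 of 123 (69.4 expected) without KMS21, 157 of 235 (127.2) without KMS27 and 367 of 740 (381.4) without KMS34, or 71 of 101 (49.5), 155 of 239 (118.7) and 271 of 639 (326.9) with centred ratios.

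The size of the difference was counted within each line, which has 1 library per state and so no replicate error. The ratios were ranked among the 9031 tested genes only, and genes under the filter can have larger ones. In KMS21, MARCKSL1 (7.98), UCHL1 (7.94), a ubiquitin hydrolase, and ITM2A (7.77) had the highest log2 ratios, and SERPINF1 (-9.12), a secreted serpin, CRIP1 (-8.57) and TMSB4X (-8.36), the actin-binding thymosin beta, the lowest. In KMS27 these were SPRR2D (5.79), HLA-DRA (4.75) and HLA-DQA1 (3.89) against RPPH1 (-5.37), the RNA of ribonuclease P, TIMP1 (-4.98), an inhibitor of matrix proteases, and SNORD15B, a small nucleolar RNA listed at 0 in KMS27R. In KMS34 they were SERPINF1 (6.43), TSPAN4 (3.80) and CDC42EP1 (3.76) against LEFTY2 (-3.25), SEMA4A (-3.06) and FGFR3 (-2.79). At least 2-fold higher or lower were 1905 and 881 genes in KMS21 (30.8% of 9031), 1980 and 496 in KMS27 (27.4%) and 271 and 133 in KMS34 (4.47%). Centring each ratio on its median, 0.30, 0.43 and 0.02, gave 1206 and 1307, 719 and 1061, and 259 and 146.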

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

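The tests of a swap, of depth and of the genes that all 3 parental lines express were chosen after the result they bear on was seen. Several results had opposite signs in different lines, by at least 1 for a gene and 0.1 for a list median, so some of them lay near 0. FGFR3 had a log2 ratio of 7.73 in KMS21 and -2.79 in KMS34. The class II antigen presentation list had medians of 3.22 and 2.79 in KMS21 and KMS27 and -0.11 in KMS34. Its 12 members in the table were low in that line, with median log2 values of 0.89 in KMS34 and 0.60 in KMS34R. Hypoxia and glycolysis genes had medians of -0.11, 0.11 and -0.18 in KMS21, KMS27 and KMS34, and the unfolded protein response had -0.83 in KMS21 and 0.46 in KMS27, where the KMS27 median of both lists turned sign with median-ratio scaling. With 1 pair of libraries per line, none of these differences between lines was tested.

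The library labelled KMS21R resembled KMS21 (r = 0.788) no more than unrelated lines resembled each other. The tables argue against a swap between lines of the series, since the lower r of the other pairs was 0.915 against at most 0.841 between lines. An exchange of labels between a parental library and its derivative leaves r unchanged, so it could not be seen this way. Estimated depth was 0.956 that of KMS21. That estimate was sought only near equal depth, so it cannot decide whether depth differed more. The tables also argue against a mixture of KMS21 with KMS27 or KMS34 cells: only 9 genes were on in this library alone, as a mixture allows (up to 20), but 14 of the 3328 genes on in all 3 parental libraries were off in it, against 1 in KMS27R and 0 in KMS34R, TMSB4X standing at 8.47, 11.6 and 10.7 in the parental lines and at 0.11 here. Of the 57 genes private to KMS21, 8 (14.0%, exact binomial 95% interval 6.26 to 25.8) were still on, against 29 of 30 and 55 of 55 in the other lines, while the highest share for an unrelated pair was 60.0%, itself of this library with genes private to KMS34, or 9.09% (3.02 to 19.95) without it. A wrong label or another line under this label therefore remains a candidate explanation, and a large change of KMS21 itself under long exposure to the drug was not tested and stays open too. The pair alone does not show which library is out of place. The library labelled KMS21 had 42 genes on in it alone, against 9 in that labelled KMS21R. A rightly labelled line with no true derivative in the series could also hold such genes, so this count cannot decide. The label of KMS21 stays open as well.

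Ribosomal protein genes were lower in the libraries labelled KMS21R and KMS27R, with line medians of -1.31 and -1.70. Gene length bias is argued against as the source of the whole drop, since the medians of other short genes were 0.37 and 0.17, a ratio to the ribosomal median of at most -0.102. Longer genes had medians of 0.28 and 0.49, so short genes lay below them in KMS27 but not in KMS21. A small part of the KMS27 drop could thus go with length. Quantile normalization left 0.523 of the median in KMS21 and 0.262 in KMS27. Ribosomal genes hold many of the top ranks that it equalizes, so it cannot decide whether a few genes took most of the counts. Had a few genes taken more of the counts in the resistant libraries, most other genes would have fallen too. Yet the medians of all tested genes were 0.30 and 0.43 in these lines. Median-ratio scaling, a single factor per library, left a median of -1.32, with -1.665 in KMS21 and -2.25 in KMS27. These values argue against that source of the drop in these 2 lines. A difference in ribosome production between resistant and parental cells stays open, as do reads shared with pseudogenes; neither was tested.

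Regrouping the 6 libraries into 3 and 3 could not test the gene count, since the real split gave 0 genes and all 10 splits had to give at least as many. With 10 splits the share is also never under 0.1. The highest of the others gave 209 genes, but it parts only the KMS21 pair, so that with cell line in the model it sets KMS21 against the library labelled KMS21R alone and repeats the difference described above. The other splits that part all 3 pairs, as the real one does, gave 0, 32 and 3.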

How the results depend on the processing

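The added alternative, leaving KMS21 out of the shared count, was chosen after the data were seen. limma's 0 genes stayed 0 in the model without the cell line block (130 at an unadjusted p under 0.05) and under quantile normalization (329), median-ratio scaling (332), no trend (473), no filter (378), the stricter filter (301) and pseudocounts of 0.1 (422) and 0.01 (409). Leaving out a line gave 0 to 89 genes. The 9 list calls became 0 with an estimated correlation and 1 with fry, and 7 to 11 in the other alternatives; without the block, class II antigen presentation was the call of the 9 that was lost. The 36 shared genes became 94 and 112 with pseudocounts of 0.1 and 0.01, 194 at 1.5-fold, 0 at 4-fold and 88 without KMS21. Counts in KMS34 (404) became 613 with no filter, 262 with the stricter filter, 682 and 761 with pseudocounts of 0.1 and 0.01, 1365 at 1.5-fold and 68 at 4-fold; in KMS21 (2786) and KMS27 (2476) they became 4789 and 4829 at 1.5-fold and 727 and 190 at 4-fold, as the filters and thresholds admit more or fewer genes by construction. Of 757 values of named genes over alternatives 728 kept their direction and side of the threshold, 21 passed it and 8 reversed, and all 21 came from leaving out KMS21 or KMS34. IRF4 reversed with median-ratio scaling (-0.011), and when lines were left out its log2 difference ran from -0.11 to 0.61, that of CRBN from -0.26 to 0.22, IKZF3 -0.24 to 0.89, CCND1 -1.53 to 0.31, MYEOV -1.09 to 0.30, FGFR3 -1.40 to 3.86 and MAF -0.0070 to 1.78. Of 306 list tests over alternatives, 231 stayed, 29 lost and 7 gained a call, and 39 turned direction. With fry, which asks about direction and not about other genes, 11 lists turned up (adjusted p): integrins 0.918, cell adhesion 0.526, mesenchymal transition 0.918, B cell markers 0.721, proteasome 0.918, drug transporters 0.526, MAPK output 0.918, cholesterol 0.918, histones 0.936, heat shock 0.849 and translocation targets 0.918. Without the block cereblon (0.755), extracellular matrix (0.984) and NF-kB (0.993) turned; with quantile normalization proteasome (0.273) and heat shock (0.961); with median-ratio scaling cereblon (0.774) and B cell (0.886). With no filter extracellular matrix (0.752), MAPK (0.816) and heat shock (0.469) turned, with the stricter filter cereblon (0.889) and WNT (0.712), and with a pseudocount of 0.1 cereblon (0.945). When lines were left out, some lists turned, with adjusted p from 0.431 to 0.994 for cereblon, 0.210 to 0.975 for extracellular matrix, 0.121 to 0.823 for vesicles, 9.14e-05 to 0.412 for the unfolded protein response, 0.0548 to 0.144 for MAPK, 0.0667 to 0.412 for class I, 2.19e-06 to 0.987 for histones, 0.0523 to 0.987 for heat shock, 0.000913 to 0.592 for proteasome, 0.0933 to 0.987 for BCL2, 0.373 to 0.987 for B cell and 0.0362 to 0.987 for translocation targets. Apart from the filters and thresholds, the cause was not tested. Count-based alternatives were not run because the table holds no counts, and the unknown depth leaves the precision of low genes open.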

Other observations

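Most markers of other cell types were at or near 0, with exceptions in single libraries and some in several. These values carry no test. Of the T and NK cell markers 6 of 18 in the table had a linear value of at least 1 in some library, and CD7, a T cell surface protein, was at 7.57 in KMS21 and listed at 0 in KMS21R, while NCAM1, an adhesion protein of NK cells and of many myelomas, was at 0.17 in KMS21 and 1.72 in KMS21R, at 2.73 in KMS27 and 2.88 in KMS27R, and at 2.16 in KMS34 and 3.53 in KMS34R. Among the epithelial markers (7 of 12), KRT8, a keratin, stood at 5.89 in KMS34R against 1.29 in KMS34, CDH1, E-cadherin, at 3.97 in KMS27R against 0.88 in KMS27, and KRT18 at 3.55 in KMS21 and listed at 0 in KMS21R. C1QB, a complement gene of myeloid cells (4 of 12), was at 3.36 in KMS34R and 0.37 in KMS34. By the same linear value of at least 1 in some library, counts were 4 of 15 for fibroblast and stromal, 2 of 11 for endothelial, 2 of 7 for erythroid and 9 of 16 for B cell markers, and the table used here held 0 mitochondrially encoded transcripts. NT5E, a stromal surface enzyme, was at 3.74 in KMS21 and listed at 0 in KMS21R. These genes were chosen after their values were seen, apart from NCAM1 and NT5E.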
